A study of Caenorhabditis elegans with 2 samples.

How the data were processed

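Whole young adult C. elegans of 1 transgenic strain, expressing ZTF-22 with EGFP and FLAG tags at its C terminus from a transgene that also carries unc-119, were profiled by ChIP-seq. Chromatin was sonicated and immunoprecipitated with an anti-GFP antibody, per the labels, and the labels name 2 biological replicates. The antibody field of the labels names ztf-22 itself. Replicate numbers were taken from the labels.

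The authors deposited region lists on ce11: 1 for each replicate, 1 for the pooled reads of both replicates and 1 of optimal peaks kept after a comparison of replicates by the irreproducible discovery rate. Per the deposited descriptions, the lists were made against the same control alignment. The peak caller, its version, the aligner, the read filters and the threshold for the optimal peaks are not given in the sources used here. The deposited signal value of each region is the authors' own, from their caller. Its median was 19.2 in replicate 1, 34.5 in replicate 2 and 48.4 in the pooled list, so values were compared between lists by rank or correlation only. The deposited q value of each region is given as -log10 q, and the highest q among the optimal peaks was 0.00822. Each candidate list holds 30000 regions, most of them with the same width within a list (356 bp in replicate 1, 404 bp in replicate 2 and 390 bp in the pooled list), and includes weak regions meant as background. The optimal list was identical to the 952 pooled regions with the highest signal value, so the replicate comparison set how many peaks were kept and not which. Alignments, coverage tracks and the control library were not analysed here. The read depth of each library is unknown, and no interval below covers it.

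Positions were counted from 1. Chromosome lengths of the reference genome (WBcel235) fitted the coordinates of all lists, and the Ensembl annotation of that build gave genes, transcript starts, exons and biotypes on the 6 nuclear chromosomes. Clone-based names were looked up in the RefSeq table, which left 5 genes without a name. A summit was placed in the first of these classes that held it: promoter window (500 bp upstream to 200 bp downstream of a protein-coding transcript start), 5' UTR, coding exon, 3' UTR, intron, non-coding gene and intergenic. A gene had a peak when a summit lay in its promoter window. Regions of different lists were matched when their summits lay within 100 bp. The background for location, chromosomes and non-coding classes was the 28851 pooled candidate regions that did not overlap an optimal peak. For each replicate alone, its 952 strongest regions took the place of the optimal peaks, and the background was the rest of its own list.

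Shares were compared with two-sided Fisher's exact tests and conditional 95% intervals of the odds ratio, motifs in a summit and its flanks with exact McNemar tests, and correlations with 100000 permutations over sites. In odds ratios with an empty cell, 0.5 was added to each cell. Intervals of shares are exact Clopper-Pearson intervals. Families of tests were adjusted by the Benjamini-Hochberg method, and the threshold was 0.05. Sites and genes are not replicates, so p-values describe sampling of sites or genes within these 2 libraries. Gene lists, non-coding classes, motifs, tests and most alternatives were fixed before the data were examined.

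Genes and peaks were named by a rule fixed before the data were examined: ztf-22 and unc-119; the genes of the 20 strongest optimal peaks with a protein-coding start in the window; up to 4 members with the highest signal value from each list that passed; members of other lists where 5 or fewer had a peak; the 5 strongest optimal peaks with no start in the window; and the 5 with the largest rank difference between replicates. The examples of non-coding genes and of motif matches were chosen after their values were seen, as was sharing of a summit by lin-54 and rpl-12.

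The alternatives covered other matching rules, the 476 strongest optimal peaks, other promoter windows, other backgrounds, each replicate left out, and other flanks and word lengths. Optimal peaks found among the strongest regions of both replicates, GC-matched candidate regions, candidate regions outside coding exons and an intestinal list without vitellogenins were added after the data were examined. GC matching drew 5 candidate regions of the same promoter status and 2% GC bin for each optimal peak, and 1 peak had no match.

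The tests of gene lists, non-coding classes, location, motifs, 6-mers and shared regions were run on simulated data. With peaks planted at 15% of the members of 3 lists among 19973 genes, all 150 planted effects in 50 simulations were recovered, and 4 of 1250 tests of other lists were called. CTGCGTCTC was planted at 8% of 952 shuffled summit sequences. The motif test recovered it in 10 of 10 simulations with 0 of 220 other calls, and the 6-mer search recovered parts of it in 6 of 10. The simulated summits, flanks and background were all shuffled from the summit sequences and had the same base composition, unlike the real ones. These simulations therefore do not cover calls that follow from GC content. Planted non-coding sites were recovered in 50 of 50 simulations, with 1 call in 300 tests of other classes. A doubled promoter odds was called in 50 of 50 simulations at a median odds ratio of 2.04, and the X share, left at chance in them, was called in 3 of 50 (6%). With 476 of 952 regions kept in place, the matching found a median of 476. The replicate correlations, the chromosome centre share, the stratified X odds ratio, the ztf-22 density and the comparisons of regions held by 1 replicate alone were not simulated. The computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.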

Results

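Young adult C. elegans carrying a transgene of the zinc finger protein ZTF-22 fused to EGFP were profiled by chromatin immunoprecipitation and sequencing with an anti-GFP antibody. The animals came from synchronised whole-animal cultures of both sexes collected at 68 hours. There was 1 group with 2 biological replicates and no second condition, so the comparisons below are between regions, genes and replicates. The values are the authors' region lists: 30000 candidate regions for each replicate, 30000 for the pooled reads, and 952 optimal peaks. The read depth of each library is unknown from these files. Each region's signal value is the authors' own, in the units of their peak caller, and was used to rank regions within a list. All coordinates are ce11.

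Of the 100 strongest ZTF-22 peaks, 34% lay in promoter windows, and several of these were upstream of genes for protein synthesis or for the endoplasmic reticulum. The peak with the highest signal value, 555, had its summit at position 3867571 of chromosome III, 283 bp upstream of rpl-3 (WBGene00004414, 3867854 to 3869587, + strand), which encodes a protein of the large ribosomal subunit. It ranked 1 in replicate 1 and 2 in replicate 2. The next peak, with a signal value of 526, had its summit at position 10759251 of chromosome III, 56 bp upstream of tasp-1 (WBGene00010480, 10759307 to 10763021, + strand), the worm homologue of the protease taspase. It ranked 2 in replicate 1 and 1 in replicate 2. Among the 20 strongest peaks with a protein-coding transcript start in the promoter window, ribosomal protein genes also appeared at rank 6 (rpl-15, divergent from K11H12.8, chromosome IV, summit 654919, signal 409), rank 17 (rpl-20, divergent from Y17G9B.5, chromosome IV, summit 4750082, signal 336) and rank 38 (rpl-35, chromosome III, summit 7854709, signal 266). The translation factor genes iff-2 (rank 46, chromosome II, summit 8561447) and drr-2 (rank 52, chromosome III, summit 13643734) were in the same set, the latter divergent from set-16, which encodes a histone methyltransferase.

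Some other members of that set were genes of the endoplasmic reticulum. The peak at rank 16 lay 205 bp upstream of sec-61.G (chromosome V, summit 10897348, signal 336), a subunit of the protein-conducting channel of the endoplasmic reticulum. The peak at rank 23 lay 294 bp upstream of serp-1.1 (chromosome X, summit 15841278, signal 312). The peak at rank 42 lay between the divergent genes trap-3 and sec-61.B (chromosome IV, summit 2389125, signal 262), which encode parts of the translocon and its associated complex. The peak at rank 44 lay 11 bp upstream of xbp-1 (chromosome III, summit 4193798, signal 261), a transcription factor of the unfolded protein response. Their ranks were 12, 72, 52 and 143 in replicate 1 and 20, 17, 51 and 40 in replicate 2.

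The remaining promoters of the set were those of cdc-48.1, a chaperone ATPase (rank 25, chromosome II, summit 10563577), H12C20.7 with nhr-68, a nuclear hormone receptor (rank 28, chromosome V, summit 11573050), and the divergent heat shock protein 70 genes F44E5.4 and F44E5.5 (rank 31, chromosome II, summit 11759483). Further members were Y48C3A.5 (rank 32, chromosome II, summit 13299644), puf-9, an RNA-binding protein of the Pumilio family (rank 34, chromosome X, summit 5841305), and ztf-7, another zinc finger protein (rank 45, chromosome V, summit 9790032). The peak at Y48C3A.5 lies within 25 kb of ztf-22, where reads may include the transgene, as described below. The last were kel-3 (rank 47, chromosome III, summit 13464616, inside ant-1.1), gcy-33 (rank 55, chromosome V, summit 12002250, inside the tRNA gene F57F5.t1) and E01G4.3 (rank 57, chromosome II, summit 13462223). The 5 strongest peaks without such a start lay at rank 3, 889 bp upstream of F16G10.6 (chromosome II, summit 2378740, signal 462, intergenic), at rank 4 in an intron of pqn-41 (chromosome III, summit 1921373, signal 438), and at rank 5 in an intron of ppfr-1 (chromosome I, summit 9382996, signal 414). The others were at rank 7 in an intron of pkg-2 (chromosome IV, summit 8527790, signal 390) and at rank 8 in the non-coding RNA gene F26F4.14 (chromosome III, summit 4899926, signal 385).

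How far the replicates picked the same places bears on every other value, since the p-values here do not cover variation between libraries. Of the 952 strongest regions of replicate 1, 434 (45.6%, 95% exact binomial interval 42.4 to 48.8) had a summit within 100 bp of one of the 952 strongest of replicate 2. Rotating the regions of replicate 1 along their chromosomes 1000 times gave a median of 2 and a highest count of 9. Drawing 952 regions at random from each list of 30000 gave a median of 9 and a highest count of 19. The optimal peaks were exactly the 952 pooled regions with the highest signal value, and 438 of them (46%, 42.8 to 49.2) matched a region among the 952 strongest of both replicates.

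Peak strength was correlated between the replicates, and the pooled ranking followed replicate 2 more closely. Across the 855 optimal peaks matched in both lists, Spearman's rho of the signal values was 0.331 and Pearson's r of their log2 values was 0.42 (permutation p = 1e-05 for each, the smallest that 100000 permutations can give). These correlations are across sites, which are not independent replicates. The peaks were also selected on the pooled signal, which can alter the correlation. Across all 9246 candidate regions of replicate 1 matched to one of replicate 2, rho was 0.368. The pooled signal value had a rho of 0.637 with replicate 1 and of 0.860 with replicate 2, and 551 and 786 optimal peaks matched the 952 strongest regions of replicates 1 and 2. The pooled list holds the reads of both replicates, so these values are in part built in, and only their difference is informative. The optimal peaks with the largest rank differences all stood far lower in replicate 1. They lay 178 bp upstream of hrg-1, a haem transporter gene (chromosome X, summit 4009159, rank 26163 in replicate 1 and 588 in replicate 2), in the non-coding gene linc-164 (chromosome II, summit 12353993, ranks 25766 and 504), and at an offset of -1213 bp from fat-2, a fatty acid desaturase gene (chromosome IV, summit 13322660, ranks 23115 and 349). The others lay in an intron of pyk-1, a pyruvate kinase gene (chromosome I, summit 9169516, ranks 23239 and 572), and in intergenic sequence nearest to R10E4.3 (chromosome III, summit 4284852, ranks 23139 and 476).

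**Figure D1:**
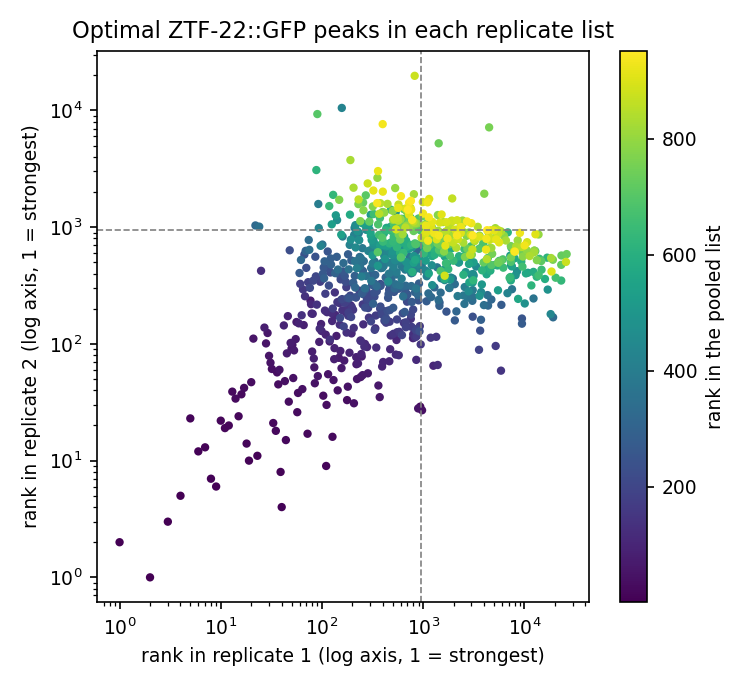
Each point is 1 of the 855 optimal peaks matched in both replicates, placed by its rank in replicate 1 and in replicate 2 on log axes and coloured by its rank in the pooled list; dashed lines mark rank 952. The 7 strongest peaks ranked from 1 to 12 in both replicates, and the 5 largest rank differences are toward low ranks in replicate 1.

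Optimal peaks lay upstream of genes and in intergenic DNA, and rarely in coding exons. Promoter windows, from 500 bp upstream to 200 bp downstream of an annotated protein-coding transcript start, held 340 of the 952 summits (35.7%, 32.7 to 38.9) against 20.3% of the 28851 candidate regions that did not overlap an optimal peak (odds ratio 2.19, 95% interval 1.90 to 2.51, two-sided Fisher's exact test, p = 2.4e-27). Intergenic DNA held 32.8% against 18.7% (odds ratio 2.13, Fisher's exact p = 2.3e-24) and introns 19.1% against 23.1% (odds ratio 0.787, p = 0.00374). Coding exons held 47 summits, 4.94% against 30.9% (odds ratio 0.116, 0.0847 to 0.156, Fisher's exact p = 1.6e-87). Within promoter windows, 296 of the 340 summits (87.1%) lay upstream of the nearest start, at a median offset of -152 bp, against 65.0% and -86 bp for the other candidate regions, in a window that itself lies mostly upstream. The upstream share was 77.9% in replicate 1 and 85.7% in replicate 2. Among the 952 strongest regions, the promoter share was 31.4% in replicate 1 and 37.4% in replicate 2, and the coding exon share was 11.6% and 4.52%.

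**Figure D2:**
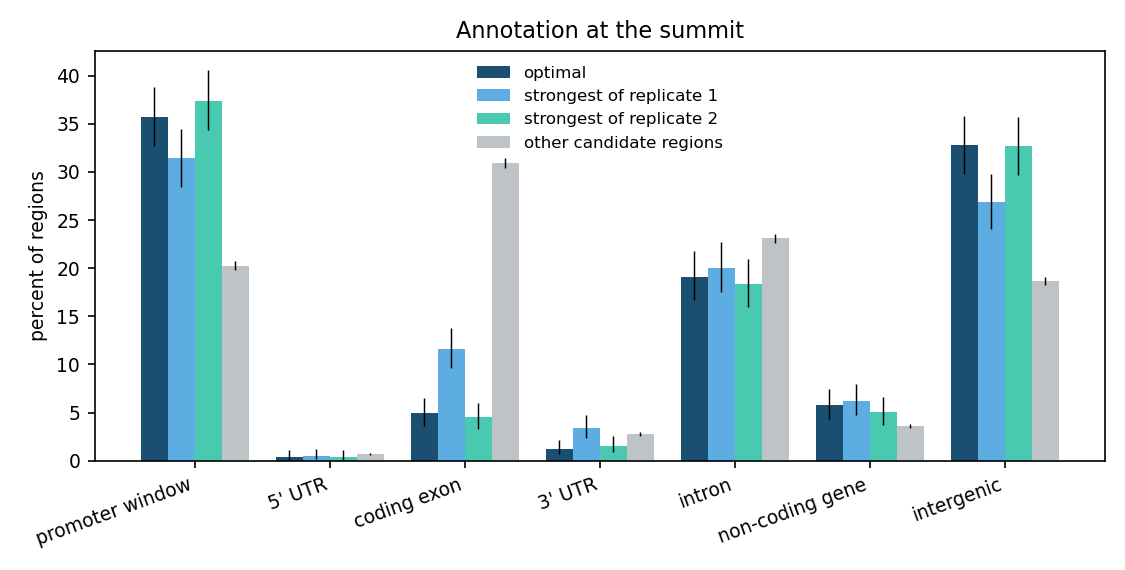
Bars give the percent of regions with their summit in each annotation class for the optimal peaks, the 952 strongest regions of each replicate and the other candidate regions, with 95% exact binomial intervals. Promoter windows and intergenic DNA held 35.7% and 32.8% of the optimal peaks, and coding exons 4.94% against 30.9% of the other candidate regions.

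Optimal peaks were denser on the X chromosome than on any autosome and favoured the middle of the autosomes. The X chromosome held 250 of the 952 optimal peaks (26.3%), or 14.1 per Mb, against 7.55 to 9.88 per Mb on the autosomes. Its share of the other candidate regions was 20.1% (odds ratio 1.42, 1.22 to 1.65, two-sided Fisher's exact test, p = 5.2e-06). The odds ratio was 1.22 (Fisher's exact p = 0.0156) for the strongest regions of replicate 1 and 1.34 (p = 0.000173) for those of replicate 2. Among the 100 strongest optimal peaks, 19 lay on X (19%, 11.8 to 28.1). On the autosomes, 445 of 702 optimal peaks (63.4%) lay in the middle 50% of the chromosome length against 52% of the other candidate regions (odds ratio 1.60, 1.36 to 1.88, Fisher's exact p = 2.4e-09).

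Ribosomal protein genes and genes of the intestine carried optimal peaks far more often than other genes, and chemosensory receptor genes far less often. A summit lay in the promoter window of 382 of 19973 protein-coding genes (1.91%). Each of 28 gene lists was tested against all other protein-coding genes with two-sided Fisher's exact tests and Benjamini-Hochberg adjustment over the lists, and 6 passed an adjusted p of 0.05. Genes are not replicates, so these p-values cover the sampling of genes only. For each replicate the same test was run on its own 952 strongest regions, and 5 lists passed in replicate 1 and 7 in replicate 2.

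Of the 82 ribosomal protein genes, 11 (13.4%) had a peak (odds ratio 8.15, 3.86 to 15.6, adjusted Fisher's exact p = 4.2e-06). The count was 11 in each replicate. The strongest were rpl-3, rpl-15, rpl-20 and rpl-35, described above. Of the 45 genes of oxidative phosphorylation, 6 (13.3%) had a peak (odds ratio 8.0, 2.75 to 19.2, adjusted Fisher's exact p = 0.00114), with 4 in replicate 1 and 5 in replicate 2. They included sdha-1 (chromosome X, summit 8546263, rank 175) and mev-1 (chromosome III, summit 10334124, rank 386), both of succinate dehydrogenase, and the cytochrome c oxidase genes cox-5B (chromosome I, summit 9788720, rank 202) and cox-5A (chromosome III, summit 12905202, rank 226). None of the 70 mitochondrial ribosomal protein genes, the 33 proteasome genes or the 48 spliceosome genes had one. The upper interval limits of their odds ratios were 2.78, 6.08 and 4.11, and none of these lists passed. Their counts therefore do not show that these genes lack peaks more often than other genes.

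Of the 29 intestinal genes, 10 (34.5%) had a peak (odds ratio 27.7, 11.4 to 63.0, adjusted Fisher's exact p = 2.4e-09). The strongest were at elt-2, the GATA factor of the intestine (chromosome X, summit 10480789, rank 133), at the cathepsin B-like protease genes cpr-6 (chromosome X, summit 6607220, rank 290) and cpr-1 (chromosome V, summit 11975412, rank 384), and at the peptide transporter gene pept-1 (chromosome X, summit 6456845, rank 372). The 6 vitellogenin genes, which encode yolk proteins made in the intestine and belong to both lists, held 4 of them: vit-5 (chromosome X, summit 3403365, rank 393), vit-3 (chromosome X, summit 3572757, rank 634), vit-2 (chromosome X, summit 5101062, rank 747) and vit-6 (chromosome IV, summit 8261008, rank 875). That gave an odds ratio of 103.7 (14.8 to 1147, adjusted Fisher's exact p = 1.3e-05). Several vitellogenin genes are near-identical copies, so reads may be shared among them, and the values at vit-2, vit-3 and vit-5 are uncertain. Sharing of reads was not examined. Without the vitellogenins, in an alternative added after the data were examined, 6 of 23 intestinal genes had a peak (odds ratio 18.4, adjusted Fisher's exact p = 2.5e-05). By replicate, 3 intestinal genes had one of the strongest regions of replicate 1 (adjusted Fisher's exact p = 0.0568) and 9 one of replicate 2 (adjusted p = 8.9e-08). For the vitellogenins the counts were 0 in replicate 1 (adjusted Fisher's exact p = 1) and 4 in replicate 2 (adjusted p = 2.1e-05). The promoters of vit-2, vit-3, vit-5 and vit-6 still held weaker candidate regions of replicate 1, at ranks 1093, 1770, 3088 and 4533.

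Of the 1309 chemosensory receptor genes, 4 (0.306%) had a peak (odds ratio 0.148, 0.0401 to 0.384, adjusted Fisher's exact p = 2.7e-06), and the replicates held 4 and 7. They were srh-2 (rank 61), srz-62 (rank 163), srv-1 (rank 279) and srh-70 (rank 843). Only 146 of them had any candidate region in the window, and against genes with a candidate region the odds ratio was 0.383 (adjusted Fisher's exact p = 0.293). Of the 42 genes of cell cycle and DNA replication, 4 had a peak (odds ratio 5.45, 1.40 to 15.2, adjusted Fisher's exact p = 0.0388): cdc-48.1 (rank 25), lin-54 (rank 207, at a summit shared with rpl-12), lin-35, the retinoblastoma homologue (rank 399), and pcn-1, which encodes the replication clamp (rank 665). This list kept its call under 3 of 8 alternatives, with adjusted p up to 0.131.

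The other 22 lists did not pass. None of the 43 germ line genes, 30 hypodermal genes, 30 neuronal genes, 31 major sperm protein genes or 176 collagen genes had an optimal peak in the window, and 1 of 30 muscle genes did (unc-60). Heat shock proteins and chaperonins had 3 of 30 (hsp-3, hsp-90 and cct-8, odds ratio 5.74, adjusted Fisher's exact p = 0.0769). Translation factors had 3 of 40 (iff-2, eef-1A.2 and eif-3.C, odds ratio 4.18, adjusted Fisher's exact p = 0.143). The first list did not include F44E5.4 and F44E5.5, nor the second drr-2, all described above with a peak. The counts and tests of these lists therefore cover the listed members only. Aminoacyl-tRNA synthetases had 2 of 31 (aars-1 and ears-2), chromatin regulators 2 of 45 (lin-54 and lin-35), zinc finger genes named ztf 1 of 25 (ztf-7) and developmental transcription factors 2 of 197 (ztf-7 and elt-2). Nuclear hormone receptors had 7 of 274, neuropeptides and insulins 1 of 141 (ins-7), histones 1 of 72 (his-37), genes of RNA interference 1 of 44 (ego-1), and detoxification enzymes 4 of 215 (gst-27, gst-9, gst-1 and dhs-25). In single replicates, heat shock proteins (4 of 30, adjusted Fisher's exact p = 0.0138) and chromatin regulators (4 of 45, adjusted p = 0.0370) passed in replicate 1, and translation factors (4 of 40, adjusted p = 0.0376) in replicate 2. C-type lectins had 3 of 240 (clec-126, clec-78 and clec-186) and the F-box and BATH families 4 of 395 (fbxa-108, fbxb-72, fbxb-85 and bath-36).

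**Figure D3:**
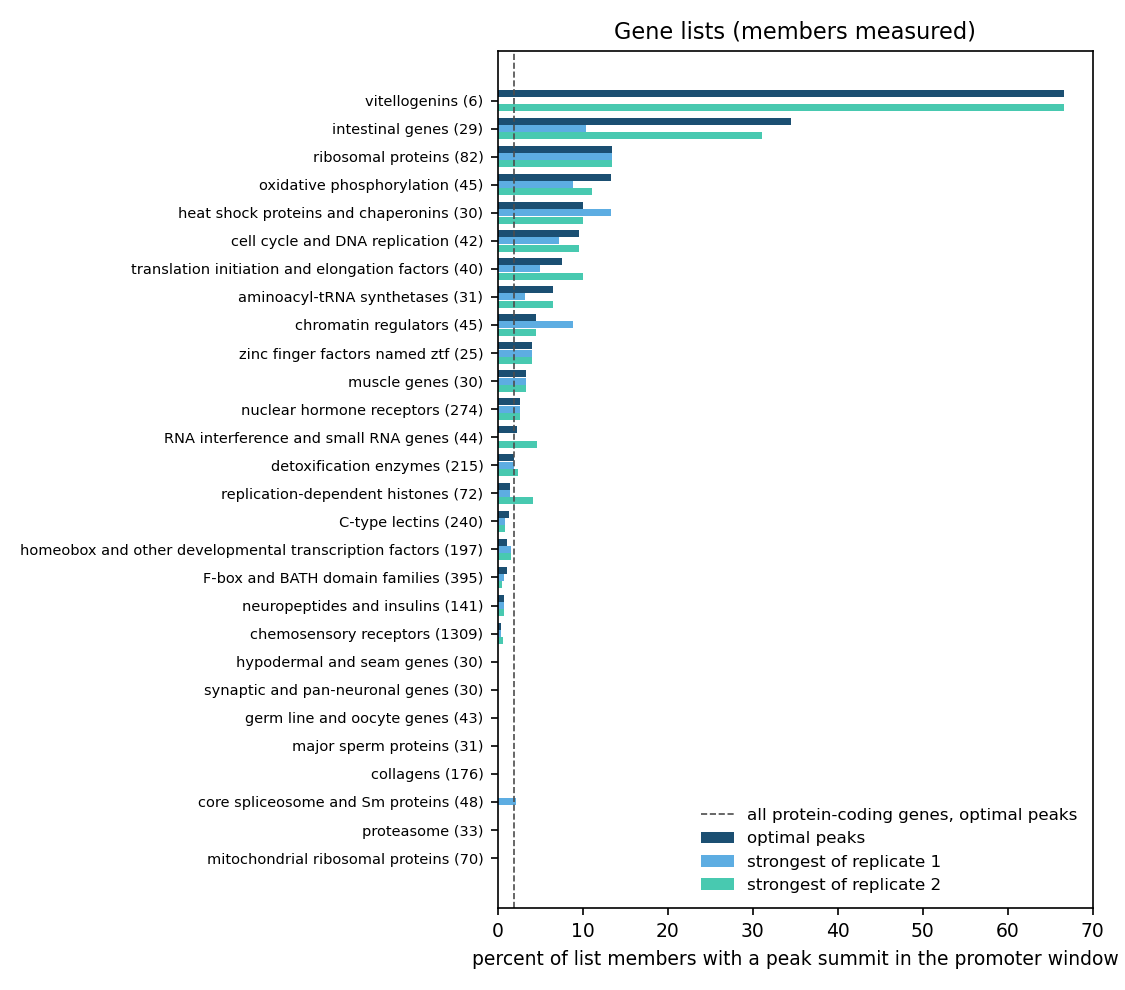
Bars give the percent of each list's measured protein-coding members with a summit in the promoter window for the optimal peaks and the 952 strongest regions of each replicate; the dashed line is the 1.91% of all protein-coding genes with an optimal peak. Ribosomal proteins stood at 13.4% in all 3 sets, and vitellogenins at 66.7% in the optimal peaks, 0% in replicate 1 and 66.7% in replicate 2. The 0% covers the 952 strongest regions only: vit-2, vit-3, vit-5 and vit-6 had weaker candidate regions in replicate 1.

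Optimal peaks lay near several classes of short non-coding genes more often than other candidate regions did. Summits within 500 bp of a member were compared with the other candidate regions, with two-sided Fisher's exact tests and Benjamini-Hochberg adjustment over 7 classes. Genes for tRNAs were near 69 optimal peaks (7.25% against 1.36%, odds ratio 5.69, 4.30 to 7.43, adjusted Fisher's exact p = 2.4e-26), with 84 of the strongest regions of replicate 1 and 51 of replicate 2. Genes for snoRNAs were near 58 (6.09% against 0.652%, odds ratio 9.89, 7.18 to 13.5, adjusted Fisher's exact p = 1.1e-32), with 47 and 60 in the replicates. Spliced leader genes, whose short transcripts are trans-spliced to the 5' ends of mRNAs, were near 7 (odds ratio 23.7, 7.49 to 71.8, adjusted Fisher's exact p = 6.9e-07), with 7 in each replicate. The 7 genes concerned were all of the sls-2 group, whose leaders go mainly to downstream genes of operons. Examples were sls-2.4 (chromosome I, summit 4172295, rank 15) and sls-2.1 (chromosome II, summit 5844834, rank 18). Genes for snRNAs, which include the spliced leader genes, were near 12 (odds ratio 5.83, adjusted Fisher's exact p = 7.6e-06), and microRNA genes near 12 (odds ratio 3.43, adjusted p = 0.000611). Genes for piRNAs were near 30 (odds ratio 1.46, 0.973 to 2.12, adjusted Fisher's exact p = 0.0645), with 26 in replicate 1 (adjusted p = 1) and 33 in replicate 2 (adjusted p = 0.0253), and rRNA genes near 0. In all, 148 optimal peaks (15.5%) lay near a tRNA, snRNA, snoRNA, spliced leader or microRNA gene, against 2.57% of the other candidate regions. Of the 148, 114 lay outside the promoter windows of protein-coding genes. Sharing of reads among similar copies of these genes was not examined. With no other tagged factor profiled here, the nearness is not shown to be particular to ZTF-22.

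The summits carried several short sequence motifs, of which the most concentrated against the flanks was CTGCGTCTC, a motif often found at worm promoters occupied by many factors. Within 100 bp of the summit it occurred at 87 optimal peaks (9.14%) against 0.840% in each flank 300 bp away and 3.47% of the other candidate regions in promoter windows. The E-box CACGTG occurred at 13.4% of summits against 3.36% and 3.05% in the flanks and 5.66% of those regions. The extended GATA site CTGATAAR occurred at 10.3% against 3.15%, 2.31% and 4.09%, the GAGA repeat GAGAGAGA at 8.51% against 2.31%, 1.89% and 3.58%, and GCGCGC at 7.67% against 1.26%, 1.16% and 3.46%. The B box of RNA polymerase III genes occurred at 2.73% against 0.315%, 0.735% and 0.445%. It lay at 24 of 612 optimal peaks outside promoter windows and 2 of 340 inside (0.588%, near the 0.445% of the other promoter regions), and it kept its call under 3 of 6 alternatives, with adjusted p up to 0.118. Of 23 motifs tested, 9 were more frequent at summits than in both flanks and the other promoter regions (exact McNemar tests for each flank and Fisher's exact test, Benjamini-Hochberg adjusted). For CTGCGTCTC the largest of the 3 adjusted p-values was 3.2e-12, and for CACGTG it was 9.4e-15.

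The other 3 of those 9 were the short GATA site WGATAR (50.3% of summits), the E-box CAGCTG (7.88%) and GGGCGG (10.2%), none of which passed in the strongest regions of replicate 1. Another 3 were less frequent at summits: the splice acceptor sequence TTTCAG (17% against 33.1% and 33.2% in the flanks), TAATTA and TTYGAA. Matches to TTTCAG were not sorted by the kind of splicing. Summits had a median GC content of 43.8%, against 35.3% and 34.8% in the flanks and 40.3% in the other promoter regions. Against candidate regions matched on promoter status and GC content, an alternative added after the data were examined, CAGCTG, GGGCGG, TAATTA and TTYGAA no longer passed. The remaining 11 motifs, among them the sites of FOXO, SKN-1, T-box, AP-1 and heat shock factors, did not pass all 3 tests.

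A search of all 2080 6-mers, made without a prior list, found a part of these sequences. On chromosomes I, III and V, 48 6-mers were more frequent within 50 bp of the summit than in both flanks, and all 10 taken to the peaks of chromosomes II, IV and X passed there (exact McNemar tests, Benjamini-Hochberg adjusted). They were parts of CTGCGTCTC (ACGCAG, GACGCA, AGACGC and CGTCTC), runs of GA (GAGAGA, AGAGAG), AGAGAC, GAGACA, GCAGAC and GCGCGC. Neither the E-box CACGTG nor a GATA site was among the 10. Only the 10 of the 48 with the smallest p-values were taken on, so that absence does not show that these sites fell short. The search compared summits with flanks only, and no GC-matched comparison was run for 6-mers. Passing on the held-out chromosomes therefore does not exclude an effect of the higher GC content at summits. On the held-out chromosomes ACGCAG was present at 12% of 533 summits against 2.44% and 1.88% of their flanks (adjusted exact McNemar p = 2.2e-09). Among the named promoters, the sequence ran GTGGAAACGAGAGACGCAGACGTCCAAGA around the match at 10897353 to 10897361 of chromosome V upstream of sec-61.G, and GCTGGCAACAGAGACGCAGATTGTTGGAG around the match at 11759505 to 11759513 of chromosome II between F44E5.4 and F44E5.5.

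**Figure D4:**
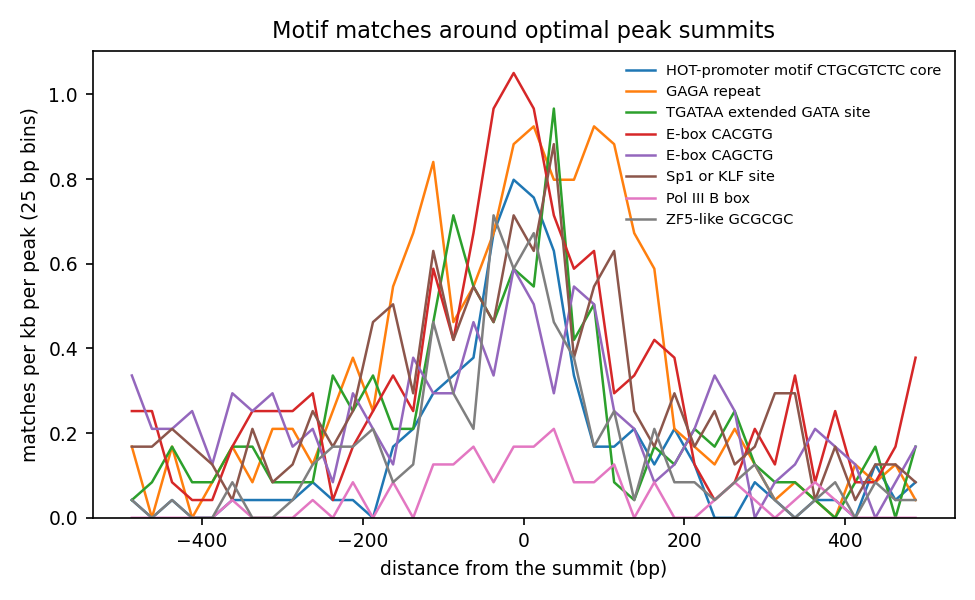
Lines give matches per kb per peak in 25 bp bins within 500 bp of the optimal summits for 8 motifs more frequent at summits; the short GATA site is left out of the plot. CACGTG and CTGCGTCTC are centred on the summit.

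The locus of the tagged gene was crowded with candidate regions. The strain carries a transgene with ztf-22 and a rescuing unc-119, so reads at these loci may include the transgene. The labels give neither its copy number nor the source of its unc-119. Within 25 kb of ztf-22 (WBGene00012988, chromosome II, 13279767 to 13285829, - strand) there were 41 pooled candidate regions, 42 of replicate 1 and 41 of replicate 2, or 7.31, 7.49 and 7.31 per 10 kb against a genome mean of 2.99. They included 5 optimal peaks. The strongest had its summit at 13298722, in an intron of Y48C3A.5, a gene that spans ztf-22, and ranked 13 in the pooled list, 110 in replicate 1 and 9 in replicate 2. Within 25 kb of unc-119 (WBGene00006843, chromosome III, 10902641 to 10908935, + strand) there were 10, 6 and 13 candidate regions, or 1.78, 1.07 and 2.31 per 10 kb, and no optimal peak, and the strongest pooled region ranked 3455. The design set no test for these loci.

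**Figure D5:**
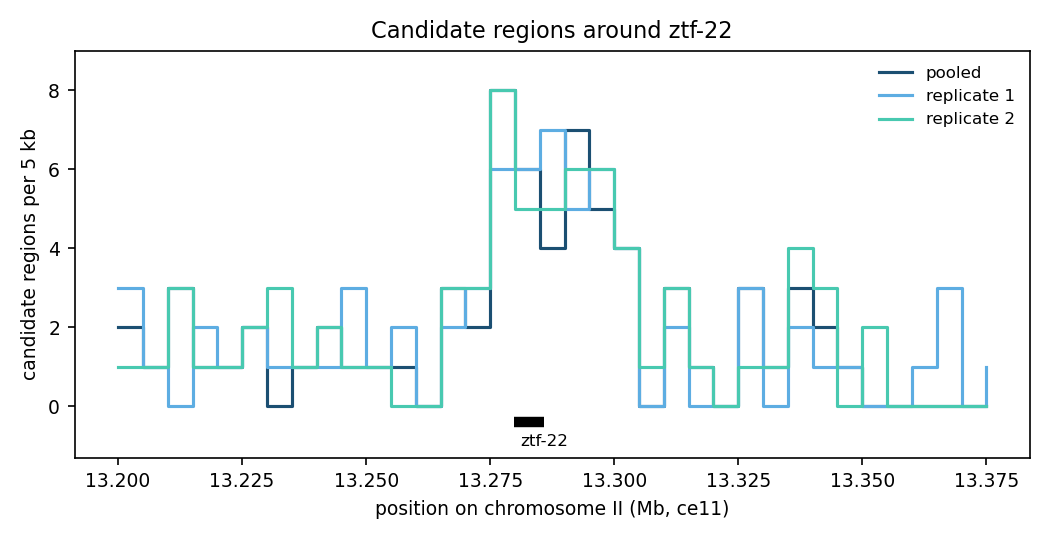
Steps give the number of candidate regions per 5 kb of chromosome II around ztf-22 (black bar) in the pooled list and in each replicate. The 6 bins from 13275001 to 13305000 held 4 to 8 regions each in the pooled list, and the other bins 0 to 3.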

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

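Of 55 alternative values of the main results, 49 kept their direction and their side of the threshold, and none reversed. The other 6 moved, and the cause was not tested. The share of strongest regions held in common went from 45.6% to 33.1% with summits within 50 bp, 50.9% with an overlap of 1 bp, 50.4% among the 476 strongest and 37.6% among the 1904 strongest. With 8-mers, 2 words passed on the held-out chromosomes instead of 10 6-mers. The strongest pooled region near ztf-22 ranked 687 within 10 kb and 13 within 25 kb, since the peak at rank 13 lies farther out. Leaving out replicate 1 or 2 gave promoter odds ratios of 2.28 and 1.87, X odds ratios of 1.34 and 1.22, and 7 and 5 gene lists past the threshold against 6. Of 405 alternative values of single lists, classes and motifs, 371 stayed on their side of the threshold, 24 lost a call and 10 gained one; direction was not read where neither value passed its test. The optimal peaks held by both replicates, an alternative added after the data were examined, gave 5 gene lists past the threshold, with heat shock proteins and chaperonins gained (adjusted p 0.0188); there the intestinal list stood at an adjusted p of 0.139 and the vitellogenins at 1. All 8 alternatives kept the calls for ribosomal proteins (odds ratio 4.32 to 15.6) and oxidative phosphorylation (4.66 to 13.3), and all 6 those for tRNA and snoRNA genes. The depth of the libraries is unknown and there are 2 replicates. A region absent from a list is below that list's 30000 strongest and not shown to be unbound. A peak without a summit match is not always absent: 942 optimal peaks overlapped a region of replicate 1 by 1 bp, against 874 matched by summit.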

Other observations

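Of the tests below, those of the ztf-22 density, of the tRNA genes, of the intestinal genes and of the GATA sites were chosen after the values they measure had been seen in part. The X chromosome, transcript start and endoplasmic reticulum tests were set before their results were known.

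Endoplasmic reticulum genes stood out among the strongest promoter peaks, at sec-61.G, serp-1.1, trap-3 with sec-61.B, and xbp-1, and no list for them had been fixed beforehand. A list of 58 genes of protein translocation, folding and the unfolded protein response was therefore written, and the 6 members already seen at a peak were set aside. Of the other 52, 6 had an optimal peak (odds ratio 6.89, 95% interval 2.39 to 16.3, two-sided Fisher's exact test, p = 0.00042): crt-1 (calreticulin, rank 661), dad-1 (rank 848), enpl-1 (rank 481), pdi-6 (a protein disulphide isomerase, rank 802), trap-1 (rank 776) and trap-2 (rank 474). With all 58 members, 12 had a peak. ZTF-22 may therefore be recovered at this class of genes more often than at others, as a hypothesis found and tested on the same libraries. By replicate, of the 52 genes, 5 had one of the strongest regions of replicate 2 (odds ratio 5.37, Fisher's exact p = 0.00347) and 1 of replicate 1 (odds ratio 1.18, p = 0.577), and the difference between the replicates was not tested.

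Each replicate held 518 of its 952 strongest regions alone, and these differed in kind. Regions of replicate 1 alone lay near tRNA genes at 10.6% and in coding exons at 18.7%, against 4.25% and 5.79% for those of replicate 2 alone. The rest of the list of replicate 1 had 1.24% near tRNA genes (odds ratio 9.47, 6.89 to 12.8, two-sided Fisher's exact test, p = 9.0e-32) and 30.6% in coding exons (odds ratio 0.523, 0.415 to 0.655). The 518 regions were thus not all like that rest, though a part of them may be. That 84 of the 952 strongest lay near tRNA genes was known beforehand, so this is not independent support. Nearness to tRNA genes also does not tell binding from other sources of signal. Extended GATA sites were more frequent in regions of replicate 2 alone (12.5% against 5.02%, odds ratio 2.72, 1.66 to 4.54, Fisher's exact test, p = 2.4e-05), but so were CTGCGTCTC (8.30% against 4.05%), promoter windows (38.0% against 27.4%) and snoRNA genes (4.63% against 2.12%), so the difference is not particular to the intestine. Intestinal genes were held among the 952 strongest regions by replicate 2 alone in 7 cases and by replicate 1 alone in 1 (exact McNemar test, p = 0.0703). Replicate 2 alone also held more of the other genes (192 against 133), so a difference particular to intestinal genes stays open. The 7 genes were not absent from replicate 1: each had a weaker candidate region there, at ranks from 1093 (vit-2) to 4533 (vit-6). The gene held by replicate 1 alone, act-5, had a candidate region at rank 1463 in replicate 2. No biological explanation was tested.

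Candidate regions crowded the ztf-22 locus in all 3 lists. Their density within 25 kb was 2.81 times that of the next 25 kb in the pooled list, 2.88 times in replicate 1 and 2.44 times in replicate 2. Of 19990 genome windows of that width, 17 held at least as many pooled regions. These windows overlapped each other and included those over ztf-22 itself, so the 17 are not separate places. A wealth of transcript starts argues poorly for it, since 7.32% of the 41 regions (1.54 to 19.9) lay in promoter windows and 26 lay in introns. Extra copies of the tagged locus could account for it, and the optimal peaks there, at ranks 13, 32, 417, 687 and 939, are then not evidence of binding to the native gene. No biological explanation was tested, and binding of ZTF-22 across its own locus stays open.

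The excess of optimal peaks on X was weighed against location and sequence content. Stratified by annotation class and GC content in 5% bins, the odds ratio of X was 1.26 (1.09 to 1.47) against 1.42 before. These properties, binned in this way, therefore did not account for the whole excess. Differences within the strata were not excluded, and the stratified value was not computed for each replicate. A signal raised along the whole of X could not be excluded: among coding exon regions, X held 17.5% of those in the 5000 strongest and 16.7% of the weaker ones (odds ratio 1.06, 0.885 to 1.27, Fisher's exact test, p = 0.489). No biological explanation was tested.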
